A study of Rattus norvegicus with 19 samples.

How the data were processed

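Gene expression was measured in the thymus of female Wistar rats, 7 weeks old per the labels, that had been gavaged once daily for 14 days with saline at 10 ml/kg or with corn oil at 2, 5 or 10 ml/kg. The labels' protocols give 6 animals per group and 3 rats per cage, so the animals of a group shared few cages, and cage was not given in the labels. Arrays were used for 5 saline animals, 5 animals at 2 ml/kg, 4 at 5 ml/kg and 5 at 10 ml/kg, 19 arrays in all. Each array was taken as a separate animal because the labels number them as replicates within a group. Saline was given only at the highest volume, so the 10 ml/kg comparison is the only one in which both groups received the same volume.

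Total RNA was isolated with Trizol and labelled with Cy3 using a low-input amplification kit, per the labels' protocols. The arrays were 1-colour Agilent rat arrays scanned and quantified with Feature Extraction 10.7.3.1, per the file headers. The values the authors deposited are spot intensities on a linear scale. The processed intensity is background-subtracted with spatial detrending, for which the file headers hold fit statistics, and per the file headers no step between arrays is named. Each array held 42877 spots of 30367 probes besides 1377 control spots, and 1390 probes were spotted 10 times. The processing between the scanner output and the series' value table is not given in the sources used here. Set against the scanner values, each column of that deposited table was the median processed intensity of each probe, held to a ceiling of 65536, multiplied by a factor of the array and rounded, on a linear scale with no centring and no log. Besides rounding, 29802 to 30030 probes per array matched this within 0.2% without the ceiling, 337 to 568 lay at it, and 1 probe of 1 array did neither, with Spearman correlations across probes of 0.998 or more. The rule behind the factor stayed unknown. Its column medians were 163, 185, 215, 201 and 124 for saline replicates 1 to 5. They were 171, 209, 233, 173 and 148 for 2 ml/kg replicates 1 to 5, and 141, 164, 146 and 145 for 5 ml/kg replicates 1 to 4. They were 119, 117, 126, 179 and 170 for 10 ml/kg replicates 1 to 5. That table was used only as an alternative.

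The main values were log2 of the processed intensity minus the 75th percentile of the array. Control spots were left out, spots marked as non-uniform or as population outliers were set to missing, and spots of the same probe were averaged. No spot was marked as saturated. The files carry accessions rather than gene symbols, so a probe was named by matching its accession, without version, to a RefSeq gene table of assembly GRCr8. The match named 17320 probes with 14623 genes and left 13047 probes under their own identifiers, of which 4149 carry only an Ensembl transcript. That table was used for names and for the order of neighbouring genes, and no coordinates are given because the arrays were designed on build rn4, per the file headers. The planned rule named genes from a symbol column, and the match replaced that step. A probe was kept when it was well above background on at least 4 arrays and had at least 2 values in every group. Of the probes of a gene the one with the highest mean was used, which left 22660 genes from 25471 probes, 12581 of them with a RefSeq symbol. Missing values numbered 1250 in 818 genes.

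Signal over background sets the precision of dim genes. Between 69.7% of spots (saline replicate 4) and 88.4% (5 ml/kg replicate 4) were well above background, and the 75th percentile of the processed intensity ran from 1852 to 2954. The number of arrays limits the precision of the rest. A gene below background on every array of a group has only a bound there. Its fold is given as "at least", from the mean of the brighter group against the mean, over arrays of the dim group, of the higher of the lowest signal well above background and its own signal.

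The arrays lay on 5 slides, and every slide held 2 groups. Slide 1 held saline replicates 3 and 4 and 2 ml/kg replicates 2 and 3. Slide 2 held 2 ml/kg replicate 5 and 5 ml/kg replicates 1, 3 and 4. Slide 3 held saline replicate 5 and 10 ml/kg replicates 1, 2 and 3. Slide 4 held saline replicates 1 and 2 and 2 ml/kg replicates 1 and 4. Slide 5 held 5 ml/kg replicate 2 and 10 ml/kg replicates 4 and 5. The slides were scanned on 4 days, slides 4 and 5 on the same day. The net signal of negative controls was 44.9 to 59.6 on slide 1, 19.5 to 21.6 on slides 2 and 3 and 30.1 to 39.7 on slides 4 and 5. Slide 3 had 173 to 590 non-uniform spots per array, and no other array had more than 62.

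The tests were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), in a fit of all 19 arrays with a coefficient per group and 15 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05, and adjusted p-values in the text come from limma unless another test is named. Each corn oil group and the equal-weight mean of the 3 was compared with saline. A slope per ml/kg over the 3 corn oil volumes and an F test of any difference among them were also taken, with saline outside both. The same fit with slide as a fixed block (11 residual degrees of freedom) gives the slide-blocked values. Its standard errors are approximate for genes with missing values, and with exact ones 449 genes passed at 10 ml/kg instead of 454. Sets of genes were tested with limma's camera at a preset correlation of 0.01 over 33 lists of cell types, pathways and responses with at least 5 tested members, adjusted over the lists. Missing values were filled with the group mean for that step. The same test with an estimated correlation and limma's fry stand beside it. Fry asks whether a list's genes move on balance in a direction, without comparing them with other genes. Lcn2 belongs to 3 of the lists, so those tests are not independent. A list's median in a comparison is the median of its genes' log2 differences. Within a slide it is instead the difference between groups in the mean of the per-array list medians.

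The groups, tests, filters, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes, for each comparison with saline and for the slope, the 10 genes with the largest rise and the 10 with the largest fall past the threshold that were well above background on every array of at least 1 compared group, leaving out names that are only accessions, clones or loci. Where fewer than 5 passed in a direction, it fills up to 5 with the smallest p-values. It adds up to 4 members with the smallest p of each list described, and 14 fixed genes, of which 12 were tested because Psmb11 and Mki67 had no probe named by the match. Results for some genes that these rules would name are not reported here. The alternatives were quantile normalization, normexp on the median spot and background signals with an offset of 50 (the files hold no mean signal), the deposited value table, no filter on dim probes, only probes well above background on all 19 arrays, every probe on its own, slide as a fixed and as a random block, the replicate number as a block, eBayes with trend and robust settings, array weights, only the groups compared, and leaving out each array in turn. The list alternatives used the pre-ranked form of camera. Scan day as a block was added after the data had been seen.

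The fits were tested on simulated data with as many genes and arrays, in which part of the genes were changed by log2 0.5, 1 or 2. The noise was drawn independently for each gene and array, without slide effects or correlation between genes. The shares and false calls below therefore do not carry over to arrays that differ by slide. For 10 ml/kg against saline, 22.9%, 46.3% and 77.8% of the changed genes of those sizes were recovered, with 2 false calls among 95. For 2 ml/kg the shares were 35.7%, 64.2% and 82.5% with 1 false call among 121, and for 5 ml/kg they were 30.4%, 52.9% and 78.9% with 8 among 121. The simulations for 2 and 10 ml/kg had the same group sizes and noise and differed only in random draws. The gap between their shares is therefore no difference in power. Figures were drawn with matplotlib 3.10.9 and tables read with pandas 2.3.3 in Python 3.11.15.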

Results

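The study asked how gavage with corn oil, a common vehicle in toxicology, affects gene expression in the thymus, the organ in which T cells mature. Whole-thymus RNA from 19 rats was measured on 1-colour arrays, with 5 animals given saline at 10 ml/kg, 5 given corn oil at 2 ml/kg, 4 at 5 ml/kg and 5 at 10 ml/kg. Values are log2 differences ± SE of those group sizes unless another number is given.

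The arrays were grouped more by slide than by liquid. The first principal component held 57.8% of the variance over 21842 genes, and slide explained 98.1% of its scores against 39.5% for group. On the second, with 9.93% of the variance, the shares were 87.1% and 58.6%. Correlations across genes between arrays of a group on the same slide were 0.983 to 0.993. They were 0.982 to 0.995 between groups on the same slide, and 0.944 to 0.989 within a group across slides. For this reason slide-blocked values are given beside the calls.

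**Figure D1:**
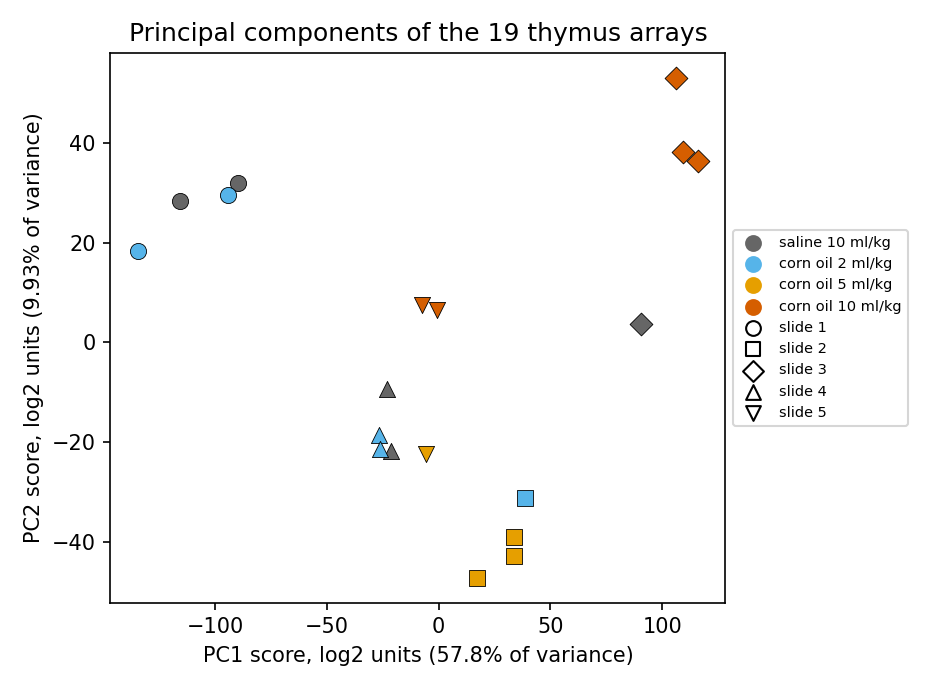
Scores of the 19 arrays on the first principal component (57.8% of the variance, x axis) and the second (9.93%, y axis), in log2 units, with colour for liquid and volume and marker shape for slide. Arrays of a slide lie together, and slide explains 98.1% of the first component's scores.

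At the volume given to both groups, 10 ml/kg corn oil against saline, several genes differed many-fold in every animal. Vegfb, a growth factor of the VEGF family, fell by 8.25 ± 0.18, with all 5 corn oil arrays not well above background and all 5 saline arrays above it, which makes it at least 84.7-fold lower (adjusted p = 1.25e-14). Mei1, which acts in meiotic recombination, rose by 5.47 ± 0.23 (adjusted p = 7.96e-11). Bad, a pro-apoptotic member of the BCL2 family, rose by 4.95 ± 0.18 (adjusted p = 1.15e-11), and Lcn2, a siderophore-binding protein of neutrophil granules, by 4.80 ± 0.21 (adjusted p = 1.40e-10). The slide-blocked differences were -8.22, 5.57, 5.35 and 5.08. Within slide 3, where 3 corn oil arrays lay beside saline replicate 5, they were -8.33, 5.48, 5.34 and 4.81. Within slide 5, where 2 of the 10 ml/kg arrays lay beside a 5 ml/kg array, they were -8.18, 5.12, 5.15 and 5.63.

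The other genes with the largest rises were the alpha globin gene Hba-a3 (4.28 ± 0.64, adjusted p = 0.000586), Ccdc146 (3.52 ± 0.29), Mpped1 (2.66 ± 0.40), the aldehyde oxidase gene Aox4 (2.56 ± 0.45), Nat8f5 (2.39 ± 0.17), the oligoadenylate synthetase family member Oas1d (2.37 ± 0.28) and Lypd8l1 (2.36 ± 0.29). The slide-blocked differences of these 7 were 6.70, 4.36, 3.67, 2.38, 2.32, 1.85 and 1.92. Hba-a3 was well above background on 1 saline array. Another probe of Mpped1 gave -1.33. The TGF-beta family gene Gdf3 fell by 4.79 ± 0.22 and the lectin gene Itln1 fell by 4.42 ± 0.32, and another probe of Gdf3 gave -4.46. The potassium channel gene Kcnd2 fell by 4.52 ± 0.81 (another probe -4.04) and Cd300lg by 4.22 ± 0.37 (another probe -0.81). Ahsg and Alb, which encode plasma proteins made by the liver, fell by 3.22 ± 0.83 (adjusted p = 0.0285) and 2.81 ± 0.67 (adjusted p = 0.0174). The vomeronasal receptor genes Vom2r73, Vom2r2 and Vom2r1 had differences of -3.21 ± 0.73, -3.12 ± 0.90 and -3.02 ± 0.73 (adjusted p = 0.0142, 0.0485 and 0.0199), and another probe of Vom2r73 gave 0.61. The slide-blocked differences of Gdf3, Itln1, Kcnd2, Cd300lg and Alb were -4.81, -3.74, -4.93, -4.23 and -3.28.

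With slide as a block, Aox4 (2.38, adjusted p = 0.0578), Ahsg (-2.95, 0.0589), Vom2r73 (-2.70, 0.344), Vom2r2 (-2.91, 0.436) and Vom2r1 (-2.62, 0.371) were no longer past the threshold, at differences near those without the block, and the other named genes of the largest rises and falls were. Normexp gave smaller differences, which were not past it, for Hba-a3 (1.70, 0.0841), Aox4 (1.37, 0.233), Gdf3 (-1.53, 0.0782), Kcnd2 (-1.12, 0.350), Ahsg (-0.43, 0.938), Alb (-1.43, 0.340), Vom2r73 (-0.55, 0.895), Vom2r2 (-1.28, 0.199) and Vom2r1 (-0.66, 0.799). In a fit of only the groups compared, Kcnd2 (0.0677), Alb (0.0766), Ahsg (0.166), Vom2r73 (0.130), Vom2r2 (0.201) and Vom2r1 (0.146) were not past it, nor were Alb (0.0630), Vom2r2 (0.0668) and Vom2r1 (0.0504) after quantile normalization. A random slide block ended the calls of Vom2r73 (0.105), Vom2r2 (0.187) and Vom2r1 (0.124). Ahsg lost its call without saline replicate 3 (0.0803) or 4 (0.0624) or 10 ml/kg replicate 1 (0.0745), 2 (0.0797) or 3 (0.0827), and Vom2r1 without saline replicate 3 (0.0544). Vom2r2 lost it in 15 of the 19 such fits, with 0.0936 without saline replicate 3 as the highest. The separation did not rest on saline alone. In 638 genes the 5 arrays at 10 ml/kg lay above (314) or below (324) all 14 other arrays, and 46 of them did so by over 1 log2 unit. Of the 12 ways to pick 3 arrays of slide 3 and 2 of slide 5, a check made after the data had been seen, no other separated more than 123 genes, or more than 1 by over 1 log2 unit.

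**Figure D2:**
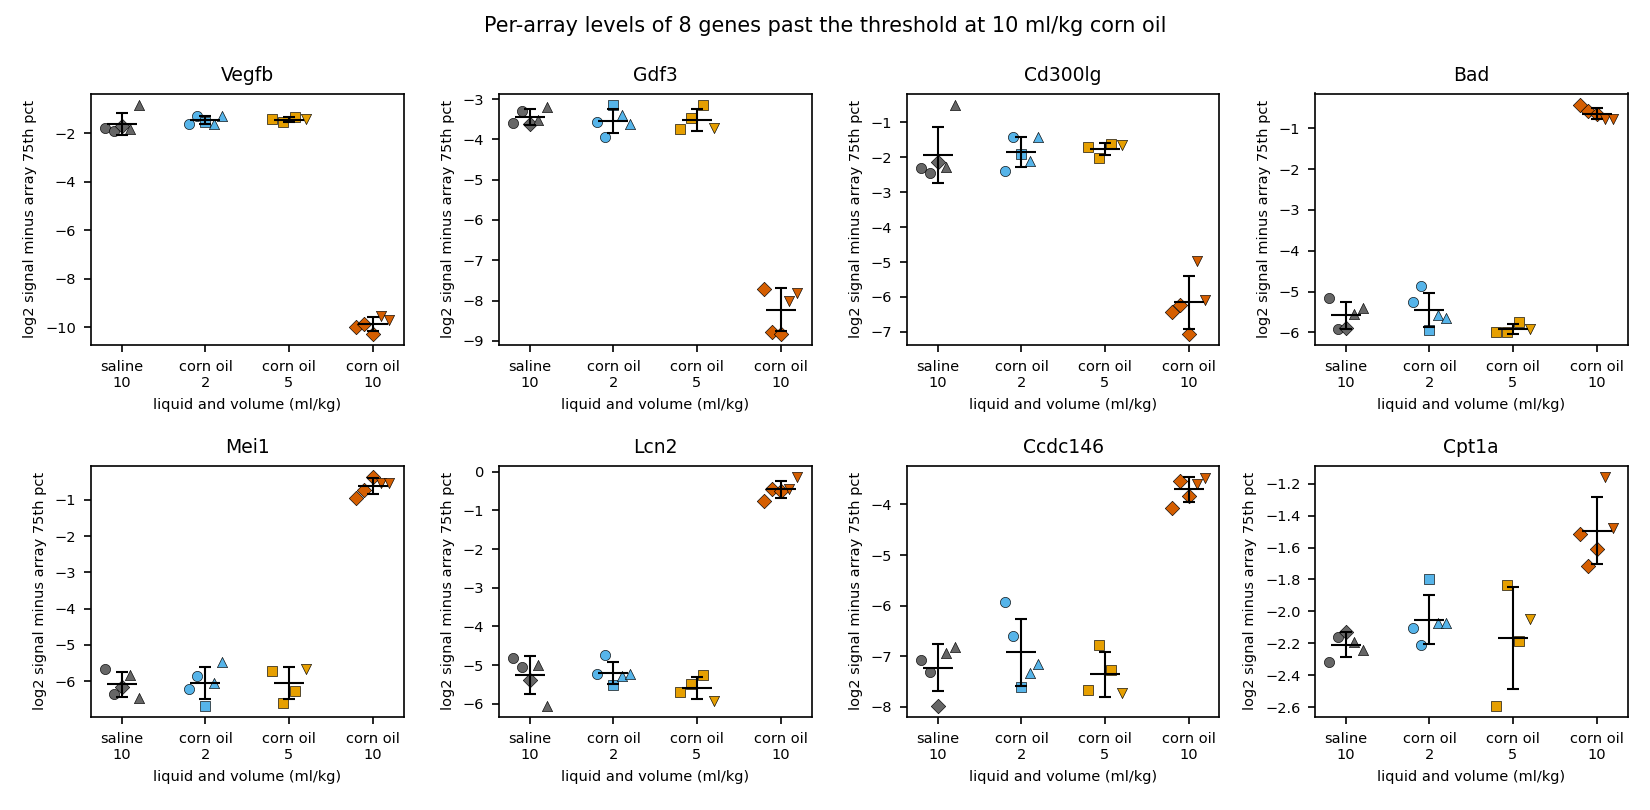
Levels of 8 genes on each array (log2 signal minus the array's 75th percentile, y axis) by liquid and volume (x axis), with marker shape for slide, and with the group mean and SD as a bar. For Vegfb, Gdf3, Cd300lg, Bad, Mei1, Lcn2 and Ccdc146 the 5 arrays at 10 ml/kg lie apart from the 14 others, and Cpt1a differs by 0.71 from saline.

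In all, 1436 of 22660 genes passed the threshold at 10 ml/kg, 634 higher and 802 lower, 848 of them with a symbol, and 553 differed more than 2-fold. Of the 203 that had another tested probe, all other probes moved the same way in 155 and some moved the opposite way in 48. The slide-blocked fit called 454 genes (260 higher, 194 lower), 328 of them among the 1436 and all in the same direction. The median difference of all genes was -0.13 here, 0.01 after quantile normalization and 0.09 after normexp, so a gene at -0.13 sat with the median gene. The share of higher genes among those called moved with it, from 44.2% to 66.7% and 74.2%, and it was 46.4% in the deposited value table. Leaving out saline replicate 3 gave 931 genes, leaving out 10 ml/kg replicate 3 gave 940, and leaving out saline replicate 5, the saline array on slide 3, gave 4691.

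Among the genes fixed for every comparison, Cpt1a, which admits fatty acids to mitochondria, rose by 0.71 ± 0.13 at 10 ml/kg (adjusted p = 0.00281), and with slide as a block the difference was 0.49 (adjusted p = 0.214). Pdk4, which restrains pyruvate oxidation, fell by 2.64 ± 0.65 (adjusted p = 0.0217). It was well above background on 2 saline arrays and no 10 ml/kg array, which makes it at least 2.12-fold lower. Of these saline arrays replicate 2 was far above the rest (-4.14), and without it the difference was -1.95 and the bound 1.31-fold. The slide-blocked difference was -1.96 (adjusted p = 0.410), normexp gave 0.0097 and quantile normalization -1.58 (0.207), and the call was also lost in a fit of only the groups compared (0.104), with a random slide block (0.131) and without 10 ml/kg replicate 1 (0.0537) or 3 (0.0626). The genes of thymocyte maturation did not pass: Dntt differed by 0.42 ± 0.17, Rag1 by -0.16 ± 0.12, Cd4 by -0.25 ± 0.11 and Cd8a by -0.17 ± 0.09 (adjusted p from 0.132 to 0.362). Dntt passed with array weights (0.56, adjusted p = 0.0153) and without saline replicate 5 (0.51, adjusted p = 0.0429). Nor did Aire (-0.06 ± 0.21), the glucocorticoid-responsive genes Fkbp5 (-0.07 ± 0.11) and Tsc22d3 (-0.20 ± 0.17), or the lipid genes Scd (-0.61 ± 0.88) and Adipoq (0.04 ± 0.88), which stood at 0.04 and 0.82 without saline replicate 2.

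At 10 ml/kg 9 of the 33 lists passed with camera, 0 with an estimated correlation and 3 by fry, and granulocyte and mast cell genes moved most clearly. All 19 tested members were positive with a median of 0.96, of which 5 were higher over all genes, 0 were lower and 14 were not called, and 13 were higher adjusted over the list alone (adjusted p = 5.40e-13). Beside Lcn2, the eosinophil granule gene Prg2 rose by 1.51 ± 0.32, the mast cell tryptase gene Tpsab1 by 0.96 ± 0.24 and the calprotectin subunit gene S100a9 by 1.12 ± 0.31. The list had an adjusted p = 0.0911 with an estimated correlation, 0.000342 by fry and 8.04e-05 with slide as a block. Its median was 0.83 with that block, 0.66 within slide 3, and 0.87 within slide 5 against 5 ml/kg. It was past the threshold without any of the 19 arrays and under every alternative run for it except the estimated correlation.

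Endothelial and fibroblast genes had a median of 0.29 over 21 members at 10 ml/kg (0.64 without saline replicate 2, adjusted p = 1.19e-07), with 5 higher, 1 lower and 15 not called over all genes, and 6 higher and 1 lower adjusted over the list alone (adjusted p = 0.00291). The value without saline replicate 2 is camera's at the preset correlation of 0.01 and does not measure the spread between animals. An estimated correlation was not run without that array. The smooth muscle gene Tagln rose by 0.90 ± 0.20, the collagen gene Col1a1 by 1.32 ± 0.30, Pdgfrb by 0.72 ± 0.18 and Pecam1 by 0.53 ± 0.14. The adjusted p was 0.653 with an estimated correlation, 0.301 by fry, 0.0109 with slide as a block and 0.0931 with scan day as a block, a setting chosen after the data had been seen. The median was 0.45 within slide 3 against saline, and 0.00 within slide 5 against 5 ml/kg.

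Lists of responses had smaller shifts at 10 ml/kg, and in all but the glucocorticoid list the called members went both ways. Of 21 unfolded protein and amino acid response genes, 2 were higher, 2 lower and 17 not called over all genes, and 6 were higher and 3 lower adjusted over the list alone (adjusted p = 0.0106, 0.109 with an estimated correlation, 0.0165 by fry). Trib3, induced by amino acid and endoplasmic reticulum stress, rose by 0.73 ± 0.10 and the transcription factor gene Xbp1 by 0.44 ± 0.08, while Pdia4 fell by 0.66 ± 0.16 and Dnajc3 by 0.44 ± 0.11. Of 23 antioxidant and xenobiotic response genes, 2 were higher, 2 lower and 19 not called, and 6 were higher and 2 lower adjusted over the list alone (adjusted p = 0.0138, 0.623 with an estimated correlation, 0.284 by fry). Txnrd1 rose by 0.57 ± 0.13 and Gpx1 by 0.34 ± 0.09, while Cyp1b1 fell by 0.76 ± 0.20 and Ephx1 by 0.52 ± 0.15. Of 23 glucocorticoid response genes, 3 were higher and 20 not called, and 5 were higher adjusted over the list alone (adjusted p = 0.0138, 0.0911 with an estimated correlation, 5.99e-05 by fry). These were Lcn2, Anxa1 (0.44 ± 0.10) and Sgk1 (0.33 ± 0.08), and Nfkbia stood at 0.38 ± 0.13. Of 32 interferon response genes, 3 were higher, 1 lower and 28 not called over all genes and adjusted over the list alone (adjusted p = 0.0168, 0.749 with an estimated correlation, 0.563 by fry). Usp18 rose by 0.58 ± 0.13, Ifi27 by 0.70 ± 0.16 and Ifit1, dim on every saline array, was at least 1.12-fold higher (adjusted p = 0.0409), while the immunoproteasome gene Psmb8 fell by 0.32 ± 0.08.

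Among the 9 tested MHC class II genes, 3 were higher and 6 not called at 10 ml/kg, and 4 were higher adjusted over the list alone (adjusted p = 0.0161, 0.653 with an estimated correlation, 0.195 by fry). RT1-DOb, whose product modulates peptide loading, rose by 1.65 ± 0.30, RT1-Db1 by 0.62 ± 0.12 and RT1-DMa by 0.39 ± 0.10, and Cd74 stood at 0.27 ± 0.10. RT1-DOb had a slide-blocked difference of 2.11 (adjusted p = 0.00434). Medullary thymic epithelium genes (median 0.04 over 17) and heat shock genes (median 0.13 over 14) both had an adjusted p = 0.0308 (0.653 with an estimated correlation, 0.368 and 0.301 by fry) with 0 members called over all genes or adjusted over the list alone. Without saline replicate 2 their medians were 0.03 and 0.05. Among their members, Krt5 stood at 0.45 ± 0.14, Ccl19 at 0.46 ± 0.15, Hspb1 at 0.66 ± 0.21 and Ahsa1 at 0.24 ± 0.10.

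None of these 7 lists was past the threshold with slide as a block (adjusted p from 0.255 to 0.961) or after quantile normalization or normexp. Within slide 3 against saline and within slide 5 against 5 ml/kg, their medians were 0.12 and 0.03 for unfolded protein, 0.08 and -0.03 for antioxidant, 0.11 and 0.14 for glucocorticoid, -0.05 and 0.38 for interferon, 0.13 and 0.46 for MHC class II, 0.07 and 0.27 for medullary epithelium and -0.03 and 0.04 for heat shock genes. Leaving out 10 ml/kg replicate 1 ended the calls of antioxidant (0.0605), medullary epithelium (0.0502) and heat shock genes (0.0622), and saline replicate 2 those of interferon (0.0625) and heat shock genes (0.0957). Saline replicate 3 ended those of interferon (0.0591) and medullary epithelium genes (0.139), and 10 ml/kg replicate 4 the same pair (0.0776 and 0.0576). Saline replicate 4 (0.0643) and 10 ml/kg replicate 2 (0.101) ended that of heat shock genes.

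**Figure D3:**
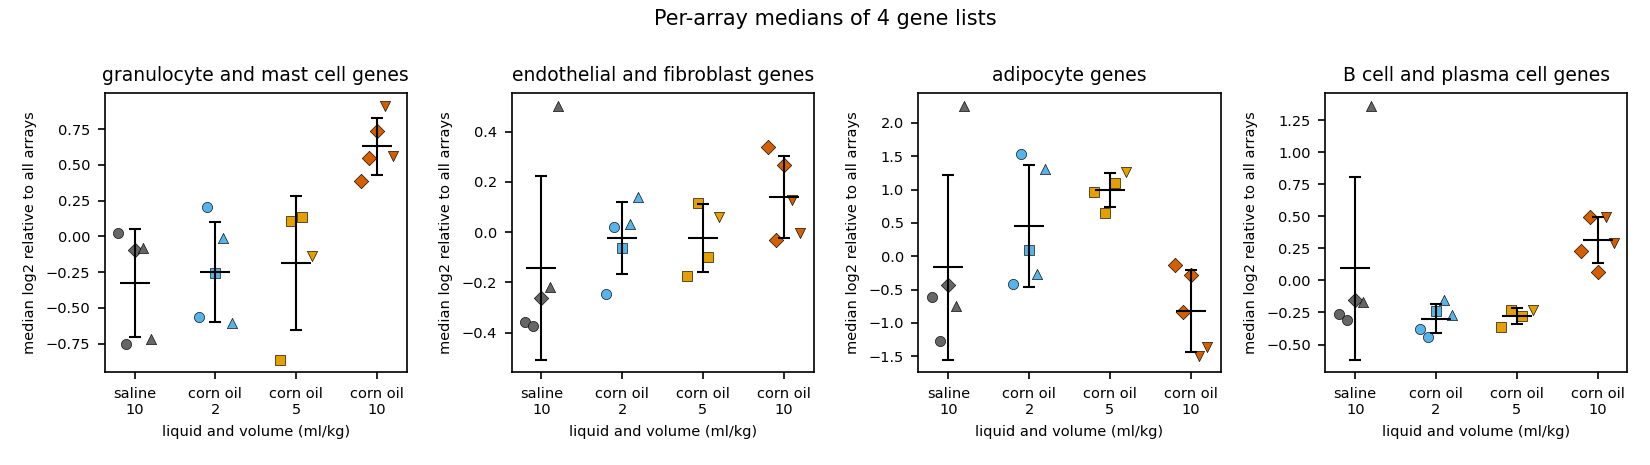
Median of each list's genes on each array, relative to the mean of all arrays (log2, y axis), by liquid and volume (x axis), with marker shape for slide and the group mean and SD as a bar. Granulocyte and mast cell genes are highest at 10 ml/kg, while adipocyte and B cell genes are highest on saline replicate 2, with medians of 2.25 and 1.36.

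At 2 ml/kg corn oil against saline, 0 of 22660 genes passed the threshold with limma, and 209 (0.922%) had an unadjusted p under 0.05. The slide-blocked counts were 0 and 576. Where nothing differs and arrays are independent, a share near 0.05 is expected. The test may thus be conservative here, and 0 calls do not show an absence of effect. The genes nearest to passing were all at an adjusted p = 1.00. Among them, values stood at 0.52 ± 0.12 for Amigo3, 1.15 ± 0.30 for Sulf1, 0.50 ± 0.14 for Dnd1 and 0.42 ± 0.12 for Dip2c. On the lower side they were Ddit4, a stress-induced inhibitor of mTOR (-0.69 ± 0.23), Tnf (-0.39 ± 0.13), Lcmt2 (-0.26 ± 0.09), Rpap2 (-0.17 ± 0.07) and Erlec1 (-0.17 ± 0.07). Of the fixed genes, Adipoq stood at 1.58 ± 0.88 and Scd at 1.42 ± 0.88 (2.36 and 2.07 without saline replicate 2), Tsc22d3 at -0.36 ± 0.17, Cpt1a at 0.16 ± 0.13 and Pdk4 at -0.21 ± 0.65. Rag1, Dntt, Cd4, Cd8a, Aire and Fkbp5 stood between -0.03 and 0.14. The median of all genes was 0.04, and 0.22 after normexp.

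At 2 ml/kg 11 lists passed with camera, 0 with an estimated correlation and 0 by fry (adjusted p of 0.862 or more), and none had a called member, over all genes or adjusted over the list alone. B cell and plasma cell genes had a median of -0.37, with 1 of 16 members positive (adjusted p = 4.46e-10). Cd79b, part of the B cell receptor, stood at -0.92 ± 0.56, Fcrla at -0.73 ± 0.38, Pou2af1 at -0.42 ± 0.24 and Blnk at -0.28 ± 0.15. The list had an adjusted p = 0.415 with an estimated correlation, 7.79e-09 with slide as a block and 0.0846 without saline replicate 2, the array with the highest B cell median, where its median was -0.05. Its within-slide medians were -0.13 on slide 1 and -0.81 on slide 4, which holds that array. Adipocyte genes were positive in 20 of 20 members with a median of 0.50 (adjusted p = 0.00088, 0.720 with an estimated correlation, 0.000507 with slide as a block), and without saline replicate 2 the median was 1.28 (adjusted p = 1.18e-19). In the corn oil arrays these members tracked each other (median correlation 0.931), far above the preset 0.01. The small p-values of this list therefore do not measure the spread between animals, and the estimated correlation was not run without that array. Car3 stood at 2.15 ± 1.03, Retn at 1.63 ± 0.96 and Cidec at 1.51 ± 0.97. The median was 1.50 within slide 1 and -0.23 within slide 4. Normexp (adjusted p = 0.0611) and leaving out saline replicate 3 (0.0615), saline replicate 4 (0.308) or 2 ml/kg replicate 4 (0.124) ended the call.

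A further 9 lists passed at 2 ml/kg with medians between -0.09 and 0.32, in fits where 0 members were called. Erythroid (adjusted p = 0.00878, median 0.32) and interferon response genes (0.0151, 0.11) were higher. MHC class II (0.00367, -0.09), natural killer and cytotoxic cell (0.00718, -0.07), cholesterol synthesis (0.00367, -0.05), inflammation and NF-kB target (0.00367, -0.05), oxidative phosphorylation (0.00439, -0.04), glucocorticoid response (0.00878, -0.03) and cell cycle genes (0.0334, -0.03) were lower. Among their members, Slc4a1 stood at 0.39 ± 0.20, Oasl at 0.29 ± 0.16, RT1-DOa at -0.38 ± 0.20, Il1rn at -0.32 ± 0.18, Klrb1a at -0.27 ± 0.20, Msmo1 at -0.18 ± 0.11 and Kif11 at -0.21 ± 0.18. With an estimated correlation the adjusted p of the 9 ran from 0.144 (glucocorticoid) to 0.869 (cell cycle). In the slide-blocked fit MHC class II, natural killer, inflammation and glucocorticoid response genes were past the threshold among these 9, at 0.00206, 0.0239, 0.000793 and 0.0319. Leaving out saline replicate 2 ended the calls of MHC class II (0.279), natural killer (0.275), inflammation (0.511), oxidative phosphorylation (0.279), interferon (0.307) and glucocorticoid response genes (0.0846). Without that array the median of inflammation genes turned to 0.03, and those of the other 8 were 0.51 for erythroid, 0.09 for interferon, -0.03 for MHC class II, natural killer and cholesterol synthesis, -0.01 for oxidative phosphorylation, -0.04 for glucocorticoid response and -0.16 for cell cycle genes. Leaving out saline replicate 5 ended that of cholesterol synthesis genes (0.162), and leaving out saline replicate 3 ended those of cell cycle (0.827, with the direction turned to higher) and erythroid genes (0.181). Each of these calls except that of cholesterol synthesis genes was also lost without 1 or more other arrays, with 0.785 for cell cycle genes without saline replicate 1 the highest of those further values. Within slides 1 and 4 the medians were 0.47 and -0.43 for erythroid and -0.29 and 0.22 for cell cycle genes, 0.09 and -0.24 for inflammation and 0.06 and 0.14 for interferon genes. They were -0.02 and -0.19 for MHC class II, -0.06 and -0.15 for natural killer, 0.02 and -0.04 for cholesterol synthesis, -0.02 and -0.07 for oxidative phosphorylation and -0.01 and -0.04 for glucocorticoid response genes.

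At 5 ml/kg corn oil against saline (n = 4 and 5), 0 genes passed with limma, while 1878 (8.29%) had an unadjusted p under 0.05. Blocking for slide gave 0 and 1236. The genes nearest to passing had an adjusted p = 0.576. They stood at 2.15 ± 0.59 for Cesl1, 0.89 ± 0.22 for the melanosome gene Mlana, 0.51 ± 0.14 for Eif4ebp2, 0.40 ± 0.08 for the splicing factor gene Sf3a3 and 0.36 ± 0.09 for Dnajb12. On the lower side were Ddit4 (-1.11 ± 0.24), Spsb2 (-0.83 ± 0.16), Fitm1 (-0.59 ± 0.13), Hip1r (-0.57 ± 0.11) and the synaptic vesicle gene Sv2a (-0.46 ± 0.10). Spsb2 alone passed in the fit without 5 ml/kg replicate 2 (-1.04, adjusted p = 0.0163). Of the fixed genes, Adipoq stood at 2.26 ± 0.93 and Scd at 1.78 ± 0.94 (3.03 and 2.43 without saline replicate 2), Pdk4 at 0.88 ± 0.69, Cd4 at -0.35 ± 0.12, Fkbp5 at 0.32 ± 0.12 and Tsc22d3 at -0.33 ± 0.18. Rag1, Dntt, Cd8a, Aire and Cpt1a stood between -0.21 and 0.04. The median of all genes was -0.01, and 0.11 after normexp.

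At 5 ml/kg 8 lists passed with camera, 0 with an estimated correlation and 0 by fry. Adipocyte genes had the largest shift, with a median of 1.43 and 19 of 20 members positive (adjusted p = 6.41e-08), and without saline replicate 2 the median was 2.11. Cidea, a lipid droplet gene of brown fat, stood at 3.07 ± 1.30, Fabp4 at 1.70 ± 0.70 and Fabp5 at 0.39 ± 0.16. The adjusted p was 0.828 with an estimated correlation and 7.37e-09 with slide as a block, and the median was 0.81 within slide 2 against the 2 ml/kg array there. No slide held both 5 ml/kg and saline arrays. Cell cycle genes were positive in 25 of 25 members with a median of 0.19 (adjusted p = 2.58e-05, 0.828 with an estimated correlation, 2.75e-07 with slide as a block), and Ccna2 stood at 0.42 ± 0.16 and Mcm4 at 0.36 ± 0.17. Without saline replicate 2 that call was lost (0.0617) and the median was 0.08 at 5 ml/kg and -0.16 at 2 ml/kg. Oxidative phosphorylation genes were positive in 30 of 34 with a median of 0.09 (adjusted p = 0.000357, 0.828 with an estimated correlation, 8.93e-07 with slide as a block). Of these, Cox5a stood at 0.53 ± 0.19, and quantile normalization (0.668) and normexp (0.516) ended the call. Within slide 2, against 2 ml/kg, the medians of cell cycle and oxidative phosphorylation genes were 0.36 and 0.16.

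Natural killer and cytotoxic cell genes were negative in all 16 members at 5 ml/kg with a median of -0.30 (adjusted p = 0.00193), and Gzmb stood at -0.41 ± 0.17 and Gzma at -0.89 ± 0.42. B cell and plasma cell genes had a median of -0.34 (adjusted p = 0.00868), with Mzb1 at -0.57 ± 0.30. Mature thymocyte and regulatory T cell genes had a median of -0.18 (adjusted p = 0.0442), with the homing receptor gene Ccr7 at -0.45 ± 0.14 and Cd69 at -0.33 ± 0.12. MHC class II genes had a median of -0.15 (0.0442) with RT1-DOb at -0.87 ± 0.32, and heat shock genes of 0.09 (0.0442) with Hspe1 at 0.24 ± 0.12. In all 8 lists, 0 members were called over all genes or adjusted over the list alone, and all 8 had an adjusted p = 0.828 with an estimated correlation and 0.240 or more by fry. With slide as a block the 5 lists of this paragraph stood at 0.00208, 0.00295, 4.62e-10, 4.91e-05 and 0.292. Leaving out 5 ml/kg replicate 1 ended the natural killer call (0.0613) and leaving out saline replicate 2 the B cell call (0.491). Without saline replicate 2 the medians of the 5 lists in the same order were -0.21, -0.09, -0.14, -0.08 and 0.05. The other 3 calls were lost in 7, 5 and 7 of the 19 such fits, with 5 ml/kg replicate 1 giving the highest adjusted p for mature thymocyte (0.306) and MHC class II genes (0.279) and saline replicate 2 for heat shock genes (0.259). Within slide 2 the 5 medians against 2 ml/kg were -0.22, -0.05, -0.28, -0.18 and 0.08.

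Averaged over the 3 volumes, 23 genes differed from saline, 14 higher and 9 lower, 15 of them with a symbol, and 1423 had an unadjusted p under 0.05. Mei1 (1.85 ± 0.19), Bad (1.58 ± 0.15) and Lcn2 (1.51 ± 0.17) rose most, and Vegfb (-2.64 ± 0.15) and Gdf3 (-1.66 ± 0.18) fell most. At 10 ml/kg Vegfb was well above background on 0 arrays and Gdf3 on 1, so the means of both depend on how signal near background is treated. These means came from the 10 ml/kg group, since at 2 and 5 ml/kg the 5 genes stood between -0.33 and 0.18 and 0 genes passed. The remaining named genes were Spata46 (0.95), Nat8f5 (0.85), the tubulin gene Tuba8 (0.62), Uqcc6 (0.57), Vsig8 (0.54) and RT1-CE16, a class I MHC gene (0.41), and on the lower side Cfap68 (-0.84), the malonyl-CoA decarboxylase gene Mlycd (-0.80), Fastkd2 (-0.63) and Wdr45b (-0.45). The fixed genes were short of the threshold, from Adipoq at 1.29 ± 0.72 and Scd at 0.87 ± 0.73 (2.07 and 1.52 without saline replicate 2) to Pdk4 at -0.66 ± 0.54 (0.04 without saline replicate 2), with Cpt1a at 0.30 ± 0.11 and Cd4 at -0.21 ± 0.09.

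With slide as a block the mean over volumes gave 44 genes, 35 higher and 9 lower, of which 14 were among the 23. Spata46 (0.87), Nat8f5 (0.70), Tuba8 (0.59), Vsig8 (0.46), RT1-CE16 (0.34), Cfap68 (-0.92) and Mlycd (-0.78) were then not past the threshold (adjusted p from 0.0671 to 0.270), at differences near those without the block. Normexp called 5 genes and of the named ones kept only Nat8f5 and Fastkd2. It gave 1.61 (adjusted p = 0.114) for Mei1, 1.43 (0.114) for Bad, 1.46 (0.0680) for Lcn2, -0.77 (0.876) for Vegfb, -0.44 (0.876) for Gdf3, -0.82 (0.0680) for Mlycd, -0.07 (0.918) for Wdr45b and 0.15 (0.927) for Cfap68, and the 5 others had adjusted p from 0.298 to 0.876. After quantile normalization Spata46 (0.240), Nat8f5 (0.0942), Vsig8 (0.163), RT1-CE16 (0.0924), Cfap68 (0.545) and Wdr45b (0.163) were not past it. The count was 14 without saline replicate 4 and 15 without saline replicate 1. Without saline replicate 4 and without saline replicate 1 the adjusted p was 0.104 and 0.0511 for Mlycd, 0.0632 and 0.0676 for Nat8f5, 0.0626 and 0.0560 for RT1-CE16, 0.0626 and 0.0676 for Wdr45b, 0.208 and 0.191 for Tuba8 and 0.127 and 0.0713 for Uqcc6. Mlycd also lost its call without saline replicate 3 (0.0766) or 5 (0.0655), RT1-CE16 without saline replicate 3 (0.0766) and Nat8f5 without saline replicate 5 (0.0572) or 2 (0.0541). Vsig8 lost its call without saline replicate 4 (0.112) and in 6 of the 19 such fits, Uqcc6 in 8, Tuba8 in 13 and Spata46 in 16, the last with 0.107 without saline replicate 4. The 5 genes that moved most and Fastkd2 and Cfap68 lost it in none.

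For the mean over volumes 7 lists passed with camera, 0 with an estimated correlation and 0 by fry. Granulocyte and mast cell genes (median 0.40, adjusted p = 2.82e-07), erythroid (0.25, 0.0164), adipocyte (0.29, 0.00277), endothelial and fibroblast (0.11, 0.0121), heat shock (0.09, 0.00847) and unfolded protein and amino acid response genes (0.07, 0.00976) were higher, and natural killer and cytotoxic cell genes (-0.21, 0.00976) lower. Of their members only Lcn2 was called over all genes, and 2 natural killer genes were lower adjusted over the list alone, where Klrb1a stood at -0.66 ± 0.16 and Ncr1 at -1.45 ± 0.37. As Ncr1 was well above background on no 10 ml/kg array, its mean depends on how signal near background is treated. Epx stood at 1.15 ± 0.46 among granulocyte genes, Hbb at 0.59 ± 0.32 among erythroid genes and Col1a1 at 0.88 ± 0.25. With an estimated correlation the adjusted p was 0.445 for the granulocyte, erythroid, heat shock and natural killer lists, 0.841 for the adipocyte and endothelial lists and 0.409 for unfolded protein genes, and by fry it was 0.273 or more. Without saline replicate 2 the medians were 1.11 for adipocyte, 0.35 for endothelial, 0.41 for erythroid, 0.04 for heat shock, 0.05 for unfolded protein, 0.38 for granulocyte and -0.15 for natural killer genes. The slide-blocked fit kept the erythroid (0.0362), natural killer (0.0147), adipocyte (0.00173) and endothelial lists (0.0297) past the threshold, and the granulocyte list was at 0.0508. Leaving out saline replicate 5 ended the erythroid (0.127), natural killer (0.0638) and endothelial calls (0.0576), saline replicate 4 the adipocyte (0.220) and endothelial calls (0.173), saline replicate 3 the erythroid (0.0785) and endothelial calls (0.250), and saline replicate 1 the same pair (0.0620 for both). Saline replicate 2 ended the natural killer (0.0607) and heat shock calls (0.0837), and 10 ml/kg replicate 1 the erythroid call (0.0512).

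Over the 3 corn oil volumes, the linear slope passed in 3461 genes, 1056 rising and 2405 falling with volume, and 1927 genes differed in any way among the volumes. The fitted slope per ml/kg was 0.72 ± 0.03 for Mei1, 0.65 ± 0.02 for Bad and 0.64 ± 0.03 for Lcn2. It was 0.54 ± 0.08 for Hba-a3, 0.53 ± 0.11 for Lrfn2 and 0.44 ± 0.04 for Ccdc146. Mpped1 (0.35), the interferon-induced gene Ifit1 (0.34, well above background only at 10 ml/kg), Nat8f5 (0.32) and Aox4 (0.32) followed. For Mei1, Bad and Lcn2 the slope rests on the 10 ml/kg group, since at the lower volumes they stood near saline, as given above. These genes belong to the 46 that set 10 ml/kg apart by over 1 log2 unit. The change of the 46 between the lower volumes was a median -0.0017 of that from the lowest volume to 10 ml/kg. These genes were chosen because every array at the lower volumes lay apart from 10 ml/kg. That choice favours a small fraction, so the fraction is no evidence on the shape of the response. The slopes of Vegfb (-1.11 ± 0.02), Gdf3 (-0.62 ± 0.03), Itln1 (-0.61 ± 0.04), Kcnd2 (-0.64 ± 0.10) and Cd300lg (-0.57 ± 0.05) were negative, as were those of Ucp1, the uncoupling protein of brown fat (-0.79 ± 0.24), Vom2r4 (-0.50), the olfactory receptor gene Or10j3b (-0.47), Ahsg (-0.47) and Vom2r73 (-0.46). At 10 ml/kg Vegfb, Or10j3b and the fixed gene Pdk4 were well above background on 0 arrays, Gdf3 and Kcnd2 on 1 and Ucp1 and Ahsg on 2. The slopes of all these genes, that of Pdk4 below included, therefore depend on how signal near background is treated. Among the fixed genes Cpt1a (0.08 ± 0.02), Dntt, the terminal transferase of thymocytes (0.06 ± 0.02), and Pdk4 (-0.34 ± 0.08) passed, with adjusted p = 0.00585, 0.0474 and 0.0115. The others did not, from Rag1 at -0.04 ± 0.01 (adjusted p = 0.0750, but 0.0472 in the deposited values and 0.0477 without 10 ml/kg replicate 3) and Scd at -0.28 ± 0.11 (0.0848) to Aire at -0.02 ± 0.03.

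Blocking for slide left the slope past the threshold in 355 genes, 186 rising and 169 falling, 302 of them among the 3461, and any difference passed in 255, with 221 among the 1927. Lrfn2 (0.48), Aox4 (0.27), Ucp1 (-0.95), Kcnd2 (-0.62), Vom2r4 (-0.48), Ahsg (-0.34), Vom2r73 (-0.37), Pdk4 (-0.27) and Cpt1a (0.06) were then not past the threshold at slopes of similar size. Or10j3b (-0.19) and Dntt (0.016) were not past it at smaller slopes (adjusted p from 0.0516 for Kcnd2 to 0.825 for Dntt). Normexp gave slopes that were not past it for Ifit1 (0.01, adjusted p = 0.916), Hba-a3 (0.13, 0.312), Lrfn2 (0.23, 0.150), Ccdc146 (0.17, 0.116), Mpped1 (0.17, 0.105), Aox4 (0.10, 0.472), Ucp1 (-0.47, 0.271), Kcnd2 (-0.21, 0.0572), Or10j3b (-0.11, 0.561), Ahsg (-0.13, 0.293), Vom2r73 (-0.14, 0.246), Dntt (0.07, 0.118), Pdk4 (-0.07, 0.775) and Cpt1a (0.07, 0.0578). Quantile normalization ended the calls of Ucp1 (0.0758), Dntt (0.0533) and Pdk4 (0.126), and a random slide block those of Lrfn2 (0.0642), Ucp1 (0.125), Vom2r4 (0.164), Vom2r73 (0.0817), Dntt (0.402), Pdk4 (0.124) and Cpt1a (0.0661). The share of rising slopes was 30.5%, against 58.7% after quantile normalization or normexp and 39.2% in the deposited value table. Leaving out 10 ml/kg replicates 1, 2, 3 or 5 gave 1696, 1609, 1657 and 5891 slopes, and leaving out 2 ml/kg replicates 2, 3 or 4 gave 1959, 1753 and 2261. For any difference, leaving out 10 ml/kg replicates 1, 2, 3 or 5 gave 1164, 1135, 1054 and 3363 genes. Dntt lost its call in 14 of the 19 such fits, with 0.134 without 10 ml/kg replicate 3 as the highest adjusted p, and Ucp1 in 7, with 0.0966 without 2 ml/kg replicate 3. Vom2r4 lost it without 10 ml/kg replicate 1 (0.0592).

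Along the slope 10 lists passed with camera, all on the higher side, 1 with an estimated correlation and 8 by fry. The median slope of all genes was -0.025 per ml/kg, and -0.00087 after quantile normalization. Camera's higher side is relative to the other genes, and fry's directions include that shift, so neither side alone shows a direction free of the scaling. Granulocyte and mast cell genes had 9 of 19 members rising over all genes and adjusted over the list alone (adjusted p = 6.70e-12), B cell and plasma cell genes 4 of 16 and 8 adjusted over the list alone (0.000107), and MHC class II genes 4 of 9 by both (0.000604). Blnk rose by 0.10 ± 0.02 per ml/kg, Mzb1 by 0.17 ± 0.04, RT1-DOb by 0.25 ± 0.04 and the mast cell gene Tpsab1 by 0.15 ± 0.03. Glucocorticoid response genes (0.000628) had 5 rising and 1 falling and were the only list past the threshold with an estimated correlation (adjusted p = 0.0181), with Lcn2, Sgk1 (0.05 ± 0.01), Nfkbia (0.07 ± 0.02) and Anxa1 (0.05 ± 0.01) rising. Inflammation and NF-kB target genes (0.00273) included Il1rn, the interleukin-1 receptor antagonist gene, at 0.17 ± 0.02 and the chemokine gene Ccl3 at -0.14 ± 0.02. The others were endothelial and fibroblast (0.00805), antioxidant (0.00805), cholesterol synthesis (0.00874), unfolded protein (0.0156) and medullary epithelium genes (0.0279), with Ccl21 at 0.09 ± 0.02 and Dhcr7 at 0.09 ± 0.02. Of these 5, with rising and falling members over all genes, endothelial genes had 4 and 1, antioxidant 5 and 2, cholesterol synthesis 2 and 1, unfolded protein 5 and 3 and medullary epithelium genes 3 and 0, and adjusted over the list alone 5 and 1, 6 and 3, 2 and 1, 6 and 4 and 4 and 0. With an estimated correlation the remaining 9 had adjusted p from 0.121 (granulocyte) to 0.675 (endothelial), and by fry the granulocyte (0.000227), MHC class II (0.0195), glucocorticoid (1.84e-06), inflammation and unfolded protein lists (0.0494 for both) passed. Fry also called 3 lists outside these 10, on the lower side, the immature thymocyte (0.0256), neuroendocrine (0.0494) and circadian clock genes (0.0494). With slide as a block the granulocyte (1.08e-05), B cell (0.000143), MHC class II (0.00997), inflammation (0.0121), glucocorticoid (0.0233) and endothelial lists (0.0233) were past the threshold in the same direction, and adipocyte genes (0.0419) passed on the lower side only with the block. The lists were not refitted with arrays left out for the slope.

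The remaining 15 lists passed with camera in no comparison unless slide was a block, with the smallest adjusted p of each between 0.110 and 0.742. They were the immature thymocyte, T cell receptor complex and signalling, cortical thymic epithelium, macrophage and dendritic cell, striated muscle, parathyroid and thyroid, neuroendocrine and nerve, fatty acid oxidation and PPAR target, fatty acid synthesis and desaturation, LXR target and lipid efflux, apoptosis, T cell cytokine and lineage regulator, immediate early, ribosomal protein and circadian clock genes. At 10 ml/kg the immature thymocyte list had a median of -0.16 with 1 of 19 members higher and 2 lower over all genes and adjusted over the list alone. The fatty acid oxidation list had a median of -0.31 with 1 of 33 higher and 4 lower over all genes, and 2 higher and 6 lower adjusted over the list alone. Without saline replicate 2, whose fatty acid oxidation median was far above those of the other saline arrays, the medians of both lists were -0.16 and -0.02. With slide as a block, 7 of the 15 passed at 5 ml/kg. Fatty acid oxidation (0.0332) and fatty acid synthesis genes (0.00468) were higher, and T cell receptor (0.00216), LXR target (0.00190), apoptosis (0.00399), T cell cytokine (0.0163) and immediate early genes (0.0124) lower. T cell receptor (0.0362) and LXR target genes (0.0297) were lower for the mean over volumes, and fatty acid synthesis genes (0.0341) lower along the slope. Of the other lists, the block added at 5 ml/kg medullary epithelium (0.00383), interferon (0.000197) and inflammation genes (0.000871) on the lower side and cholesterol synthesis genes (0.0135) on the higher. It added mature thymocyte genes on the lower side at 2 ml/kg (0.0239), 10 ml/kg (0.0212) and for the mean (5.39e-07), heat shock genes on the higher side at 2 ml/kg (0.0239), and cell cycle (0.0175) and oxidative phosphorylation genes (0.0279) on the higher side for the mean. As no slide held both 5 ml/kg and saline arrays, the blocked values at 5 ml/kg rest on links through other groups.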

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

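Of the tests below, those of slide, with all splits within slides, of saline replicate 2 and of the variation within saline were chosen after results were seen, and those of a graded response and of random splits before.

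The level of 1927 genes differed among the 3 corn oil volumes, and the 10 ml/kg arrays stood apart from all others. A slide effect as the whole cause was argued against but not excluded. With slide as a block 454 genes passed at 10 ml/kg, and the 90 splits within slides that moved those arrays gave at most 108. Those 90 share the few placements that slides 3 and 5 allow, so they set no share under 0.05. The block kept 328 of the 1436 calls and the direction of all 1436, and slide or lost precision may lie behind the lost calls. Only slide 3 held both 10 ml/kg and saline arrays, with saline replicate 5 its only saline array. The blocked values at 10 ml/kg therefore rest on that array and on links through the other groups. Of 100 splits within slides 8 gave 454 or more, the real 1 and 7 that kept these arrays in place, and of the 12 ways to place them within slides 3 and 5, too few for a share under 0.05, only the real 1 separated as many as 638 genes (highest other 123). A response in a straight line with volume was argued against but not excluded for the 1436 called genes as a set. Their 5 minus 2 ml/kg difference was a median 0.0700 of the 10 minus 2 ml/kg difference (quartiles -0.0971 and 0.267), and 0.0828 with slide as a block. It went in the 10 ml/kg direction in 885 (61.6%), so single genes could be graded. The genes were chosen by their 10 ml/kg difference, which can lower this fraction, and genes chosen in another way were not tested. A step between 5 and 10 ml/kg and a difference of these animals unrelated to corn oil stay open, and the authors' scaling was not used.

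Random splits of the compared arrays set how many calls chance gives. For 10 ml/kg against saline, 5 of 100 splits, the real one among them, called 1436 genes or more, and the highest other split, which put 4 arrays of slide 3 on 1 side, called 6833, so chance was not excluded by that count, and with slide as a block the real split called 454. The real split was among 2 of 100 for the mean over volumes (highest other 1212), 1 of 100 for the slope (highest other 1) and 2 of 100 for any difference (highest other 2959). These splits ignore slide, so they do not exclude chance there. With slide as a block and splits made within slides, 3 of 100 gave the 44 genes of the mean or more (highest other 49). For the slope 5 of 100 gave the 355 genes or more (highest other 640), and for any difference 5 of 100 gave the 255 (highest other 325). All others that gave as many kept the 10 ml/kg arrays in place, and the 90 that moved them gave at most 13, 21 and 26. The counts thus follow where those arrays lie, which slides 3 and 5 allow in only 12 ways. Chance was therefore not excluded by these counts, for the mean or for the others. For 2 and 5 ml/kg, where 0 genes were called, every split must call as many (100 of 100), so that count decides nothing. The highest other splits called 3218, following slide 1, and 3.

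Saline replicate 2 held the highest saline medians of adipocyte genes (2.25, the next at -0.44) and of B cell and plasma cell genes (1.36, the next at -0.15), far from the other 4. Of 100 genes outside the lists, chosen without saline as tracking the adipocyte median in the corn oil arrays, 84.0% had their highest saline value in replicate 2, against 18.5% of all genes outside the lists, so fat in or around that thymus may be the source. For lymphoid tissue the same test cannot tell, as 17.0% of genes chosen to track the B cell list did so but its members did not track each other in those arrays (median correlation 0.0536). Whether corn oil moved these genes was not decided. The per-array adipocyte median ranged over 3.52 within saline, against 1.16 between its group means at 5 ml/kg and in saline. Without replicate 2 these values were 0.836 and 1.76. They are differences of per-array medians, unlike the medians of gene differences given elsewhere. An exact permutation of corn oil against saline in the per-array medians (0.32) gave p = 0.588 over 11628 splits. It kept replicate 2 and pooled volumes of opposite sign (means 0.99 at 5 ml/kg and -0.82 at 10 ml/kg). Without this array the median difference of adipocyte genes was 1.28, 2.11 and -0.06 at 2, 5 and 10 ml/kg and 1.11 for their mean, and that of B cell genes at 10 ml/kg was 0.64.

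With those, arrays lay far from the rest of their group in 15 of 180 groups of values examined, where chance gives about 1 in 20. Saline replicate 2 also held the highest saline medians of macrophage and dendritic cell genes (0.36), MHC class II genes (0.27), endothelial and fibroblast genes (0.50) and fatty acid oxidation genes (0.66), and the highest saline value of Pdk4 (-4.14). Saline replicate 5 had the lowest median of parathyroid and thyroid genes (-0.54), and saline replicate 3 of immediate early genes (-0.20). At 10 ml/kg, replicate 1 had the highest median of cholesterol synthesis genes (0.20) and replicate 3 the lowest of inflammation genes (-0.17). At 5 ml/kg, replicate 2 had the lowest median of oxidative phosphorylation genes (0.043) and replicate 1 the highest Fkbp5 (2.14). At 2 ml/kg, replicate 3 had the highest median of ribosomal protein genes (0.12) and replicate 5 the highest Cd8a (4.10).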

How the results depend on the processing

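The only test here chosen after results were seen is scan day as a block. Of 60 called values of named genes, the every-probe fit kept all 60, array weights 59 and trend and robust eBayes 58, while 57 were kept in the deposited values and 56 with no filter on dim probes. The every-probe fit took each gene's value from the same probe as the main fit, so it does not show whether other probes agreed. A random slide block kept 45, quantile normalization 47, a fixed slide block 35 and normexp 23. With only the groups compared 38 of 45 were kept, and all 20 of those tested with probes well above background on all 19 arrays. Leaving out single arrays ended 101 of 1140 calls, in 15 of the 60 results. Signs that turned where neither value passed are not counted as reversed. Signal over background limits dim genes, and the slope's lists were run only with the correlation, fry and slide block settings.

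Where results changed, the cause was not tested. Quantile normalization gave 4 lists at 5 ml/kg, 2 at 10 ml/kg, 4 for the mean over volumes and 2295 slopes. Normexp gave 325 genes and 3 lists at 10 ml/kg, 5 genes for the mean, 448 slopes and 322 genes with any difference, and it turned Pdk4 at 10 ml/kg to 0.0097 and Cfap68 in the mean to 0.15. With no filter, 5 lists passed at 5 ml/kg and 12 for the mean, and with probes well above background on all 19 arrays 2 passed at 10 ml/kg. A fixed slide block gave 18 lists at 5 ml/kg, 454 genes and 3 lists at 10 ml/kg, 44 genes for the mean, 355 slopes and 255 genes with any difference. A random slide block (correlation 0.507) gave 16 lists at 5 ml/kg, 899 genes and 2 lists at 10 ml/kg, 939 slopes and 673 genes with any difference. Scan day gave 1 gene at 2 ml/kg, 14 lists at 5 ml/kg, 4 lists at 10 ml/kg, 63 genes and 4 lists for the mean, 776 slopes and 481 genes with any difference. Array weights gave 6490 genes at 10 ml/kg, 39 for the mean, 9067 slopes and 9021 genes with any difference. With only the groups compared, 4 lists passed at 5 ml/kg and 470 genes at 10 ml/kg. With an estimated correlation 0 lists passed at 2, 5 and 10 ml/kg and 0 for the mean, from 11, 8, 9 and 7.

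Leaving out single arrays gave 0 genes at 2 ml/kg and 0 to 1 at 5 ml/kg (1 without 5 ml/kg replicate 2). It gave 931 (without saline replicate 3) to 4691 (saline replicate 5) at 10 ml/kg, 14 (saline replicate 4) to 27 (10 ml/kg replicate 1) for the mean, 1609 (10 ml/kg replicate 2) to 5891 (replicate 5) slopes, and 1054 (10 ml/kg replicate 3) to 3363 (replicate 5) for any difference. Lists passing ran from 6 (2 ml/kg replicate 4) to 11 at 2 ml/kg, 5 (2 ml/kg replicate 3) to 13 (5 ml/kg replicate 3) at 5 ml/kg, 6 (10 ml/kg replicate 1) to 12 (replicate 3) at 10 ml/kg and 6 (10 ml/kg replicate 1) to 11 (saline replicate 2) for the mean.

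Replicate numbers did not pair arrays across groups: the median correlation was -0.02 over 27 pairs with the same number, 6 of them above 0.1, and 0.01 for other numbers, and 6 of 19 arrays correlated best with their own number. Arrays of a slide had a median of 0.38, against -0.06 for other slides. With the number as a block, 5 lists passed at 5 ml/kg, 14 genes for the mean, 2148 slopes and 1249 genes with any difference, and 49 of the 60 values were kept.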

Other observations

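Of the tests below, the comparison sets of genes that track Adipoq or differ between slides in the order of genes were chosen after results were seen, as were the genes named next.

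Besides the genes named in the report, others separated the 5 arrays at 10 ml/kg from all 14 others by over 1 log2 unit. Against saline, Gucy2g (2.34), Spata46 (2.28), Cenpt (2.14), Adm2 (1.97), Copg2 (1.73), Uqcc6 (1.69) and the class I MHC gene RT1-CE16 (1.35) were higher. Mmp16 (-2.62), Mlycd (-2.42), Cfap68 (-2.38), the Wnt inhibitor gene Sfrp2 (-2.23) and Fastkd2 (-1.67) were lower.

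Such all-or-none differences in unrelated genes could arise if the 10 ml/kg animals differed from the others in genetic background, and 2 tests of that were written before they were run. Called genes lay next to each other 1.63 times as often as in shuffled orders (93 pairs against a mean of 57.1 and a highest of 81 in 1000 shuffles), against 1.01 and 1.16 for as many top genes at 2 and 5 ml/kg, which met the written outcome. Genes that track Adipoq (1.43) and genes that differ between slides (2.35) did so too, and with pairs sharing their first 3 letters left out the ratios were 1.41 for called genes, 1.41 for those tracking Adipoq and 1.16 for those differing between slides, so the test cannot tell (top genes with slide as a block 1.35, all separated genes 2.26). The other probes of a called gene all moved the same way at an unadjusted p under 0.05 in 101 of 203 genes (49.8%), against 16 of 25 genes that track Adipoq (64.0%), Fisher's exact p = 0.207. The written outcome counted that p as evidence against the hypothesis, which was wrong because a p that misses the threshold with 25 genes excludes nothing, so the label was set to cannot tell after the result was seen, and the hypothesis stays open.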
